A study of Homo sapiens with 6 samples.

How the data were processed

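Polyadenylated RNA of 6 HepG2 libraries in 3 groups of 2 was sequenced after Trizol extraction and stranded TruSeq preparation. The deposited table holds counts, which the authors give as raw values per Ensembl gene, and TPM, which the authors scaled by gene length and library total. The submitters' notes name cutadapt 3.5, STAR 2.7.8a and limma, and the builds GRCh38 and GRCm38.p6; the counting tool, the annotation release and the counting strand are not given in the sources used here. The single-cell and spatial data of the series were not analysed here. Each library held between 19155876 and 22591765 counts, so that 3 counts, the limit that a count of 0 allows, correspond to 0.129 to 0.159 CPM in a library. Folds against a group at 0 counts are lower bounds computed with 3 counts over the group, and ratios against 1 to 3 counts carry a 95% counting interval. Reads without molecular identifiers are not independent molecules.

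Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr, robust quasi-likelihood F test) in 1 fit of all 6 libraries with 3 residual degrees of freedom, and p-values were Benjamini-Hochberg adjusted over the 16115 genes tested, with a threshold of 0.05. Of these, 1677 had no symbol. The common biological coefficient of variation was 9.67%. The 3 comparisons were collagen against control, CAF medium against control, and CAF medium against collagen; standard errors are the size of the log2 fold change divided by the square root of F. Gene lists, 25 with 559 genes, were tested where at least 5 members were measured. The tests were camera of limma 3.58.1, at a preset correlation of 0.01 and at an estimated correlation, and fry. P-values were adjusted over the lists of a comparison. With an estimated correlation camera tests with the 3 residual degrees of freedom, far fewer than at the preset correlation, so few lists can pass. At the preset correlation the degrees of freedom come from the number of genes tested, not of libraries. The groups, comparisons, tests, lists, rule for named genes and all alternatives except those named below were fixed before the data were examined. The rule named, per comparison, the 10 largest rises and falls among genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 1 and groups that did not overlap, the 4 members of each list with the smallest p, and KRT7, KRT19, SOX9, EPCAM, SPP1, ALB, APOA1, HNF4A, AFP, CCN1 and CCN2. Results of 3 genes that the rules would name are not reported here. Figures show CPM with TMM factors and were drawn with Python 3.11.15 and matplotlib 3.10.9.

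Alternatives were RLE normalization, no filter, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, a replicate block, only the 4 libraries compared, leaving out each library, and a fold change of at least 2-fold. Chosen after seeing the data were limma on log2 of TPM + 1 without TMM factors, a GC content and length offset, a crossed replicate block, and leaving out mitochondrial mRNAs. GC content, length and coordinates came from GENCODE 29, which held 14972 of the tested genes. The test was tested on simulated data, 10 simulations per comparison with 200 genes changed, none of them with low expression in control. It recovered on average 85.3%, 83.5% and 82.8% of 2-fold changes and 98.1%, 97.6% and 97.6% of 4-fold changes. On average 10.3%, 8.86% and 8.59% of its calls were false, above the nominal 5%. Of the unchanged genes 4.87%, 4.80% and 4.90% had an unadjusted p under 0.05 in this test.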

Results

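Messenger RNA was sequenced from HepG2, an established human liver tumour cell line, after culture in complete medium (control), on a collagen I coating of 5 µg per cm² for 2 days (collagen), or for 2 days with 20% conditioned medium of a single cancer-associated fibroblast culture (CAF medium). The labels give no culture time for the control, so time in culture may differ between the control and the treatments. Each of the 3 groups held 2 libraries, numbered 4 and 5. The series title concerns liver tumour cells with bile duct cell features and their fibroblast niche. The comparisons ask how a collagen I coating and fibroblast-conditioned medium each changed the transcripts of HepG2. No group received medium conditioned by other cells, so secreted fibroblast factors cannot be told apart from other effects of used medium. The libraries held between 19155876 and 22591765 counts, and 16115 of 78899 genes had enough counts to be tested. Mitochondrially encoded transcripts took 10.6% to 11.6% of the counts, and ALB took 3.07% to 3.51% in control, at most 1.60% with collagen, and 1.57% to 1.98% with CAF medium. Counting intervals and floors cover counting error only. In each called gene both libraries of a group lay beyond both of the other. Chance gives this in 33.3% of unselected genes, but calling selects for it, so it adds no support. Values are normalised read counts (CPM) as mean ± SD with n = 2 per group, and log2 fold changes carry their standard error. The labels do not say whether the replicate numbers stand for separate cultures, so the p-values of genes then measure only the spread between these samples. Camera p-values at the preset correlation rest on the spread between genes instead. However small, they do not measure the spread between cultures. Genes are called at an adjusted p under 0.05. A first principal component with 60.8% of the variance ordered control, collagen and CAF medium, and the collagen and CAF medium pairs differed more within the group than the control pair, with chi-square per degree of freedom of 10.97, 16.5 and 4.26.

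With collagen, 14 of 24 acute phase genes and 7 of 20 bile duct cell genes rose in HepG2, and 20 of 23 sterol synthesis genes fell. These lists passed at a preset but not at an estimated correlation (adjusted p = 0.148, 0.180 and 0.148 with an estimated correlation). The second setting also tests with 3 degrees of freedom, so the 2 settings differ in more than the correlation. KRT19, a bile duct cell keratin (chromosome 17, 41523617 to 41528308, GRCh38), rose 22.7-fold from 0.284 ± 0.197 to 6.43 ± 0.896 CPM (log2 4.51 ± 0.35, adjusted p = 3.95e-06, edgeR). Its control level was low, since 3 counts correspond to 0.145 and 0.159 CPM in the control libraries. Over the alternatives its log2 fold change was 2.95 to 5.42, so the size of the rise is uncertain. SPP1, which encodes osteopontin, rose 3.92-fold from 360.4 ± 1.36 to 1413 ± 168 CPM, and TAGLN, an actin-binding protein gene, rose 21.2-fold to 83.2 ± 6.45 CPM. ALB, the albumin gene (chromosome 4, 73397114 to 73421412, GRCh38), was 2.24-fold lower, at 14862 ± 1015 against 33219.9 ± 3050.0 CPM (adjusted p = 0.000103). In all, 2499 genes changed, 1222 higher and 1277 lower, of which 675 changed at least 2-fold.

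The remaining genes with the largest rises were SOCS3, LBP, SLC38A8, CXCL2, CA9, CD109, DNAH5 and SERPINA3. SOCS3, a feedback inhibitor of cytokine signalling, had 0 counts in control and 244 with collagen, at least 74.1-fold higher against a floor of 3 counts over the group. LBP, the lipopolysaccharide-binding protein gene, had 0 and 17 counts, at least 5.16-fold higher. CXCL2, a chemokine gene, had 1 count in control and 51 with collagen, a ratio of 46.4 with a 95% counting interval of 7.97 to 1870.2. SLC38A8 had a ratio of 73.8 with an interval of 20.1 to 614, and DNAH5 a ratio of 22.8 with an interval of 3.73 to 935. CA9, a carbonic anhydrase gene, rose 29.7-fold, CD109 19.1-fold and SERPINA3, the antichymotrypsin gene, 18.2-fold. The largest falls were in HTR1D (8.06-fold lower), PGLYRP2 (7.19-fold), PTGS1 (6.65-fold), BANK1 (5.60-fold), DMRTC2 (5.18-fold), ADAM11 (5.09-fold), NEB (4.99-fold), CNIH2 (4.03-fold) and TNFAIP2 (3.94-fold), and in the pseudogene CYP2AB1P, whose counts are uncertain. The calls of LBP, CA9 and PTGS1 were lost without control replicate 4 and without control replicate 5, that of LBP also without collagen replicate 4 and on TPM and that of CA9 with limma-voom. That of PTGS1 was also lost without either CAF medium library, with no filter and with only the 4 libraries compared. The call of TNFAIP2 was lost on TPM (0.0680). The adjusted p of LBP, CA9 and PTGS1 reached 0.122, 0.180 and 0.198 over the alternatives.

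Of the list of acute phase and STAT3 response genes, 14 of 24 measured members rose and 0 fell with collagen, 16 and 0 adjusted over the list alone. The median log2 fold change was 0.79, also with SOCS3 and LBP at their lower bounds, and the list passed the camera test at a preset correlation (adjusted p = 7.51e-23; adjusted p = 0.148 with an estimated correlation). CEBPD, a transcription factor gene, rose by 2.19 ± 0.13 and STAT3 by 0.84 ± 0.077 on the log2 scale. Of the biliary list, 7 of 20 measured members rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 5.17e-07, adjusted p = 0.180 with an estimated correlation). Its risers included CD24 (2.10 ± 0.10) and KRT23 (1.87 ± 0.16), whereas EPCAM at 0.10 ± 0.077 and SOX9 at -0.24 ± 0.088 did not pass. KRT7 was below the filter, with 0 and 3 counts in control, 11 and 4 with collagen, and 4 and 10 with CAF medium. Of the hepatocyte list, 5 of 33 measured members rose and 14 fell (6 and 15 adjusted over the list alone), the median was -0.42 and the mean -0.025, and the list did not pass (camera adjusted p = 0.109; adjusted p = 0.627 with an estimated correlation). SERPINC1, the antithrombin gene, fell by 1.39, TTR, the transthyretin gene, by 1.03, AFP, a fetal liver gene, by 0.67 and APOA1 by 0.87 on the log2 scale, and HNF4A, a liver transcription factor gene, fell by 0.46; the HNF4A call was lost without control replicate 5 (highest adjusted p 0.0612) and that of AFP without any one control or collagen library and on TPM (0.202). FGG, a fibrinogen gene and acute phase transcript, went the other way in this list at 3.23 ± 0.16. Without collagen replicate 5 the camera test of the hepatocyte list turned to higher (adjusted p = 0.0126) although its median stayed at -0.36, and without control replicate 4 the list passed as lower (adjusted p = 0.0328). It also passed as lower with no filter (adjusted p = 0.00126), limma-voom (0.0114), the GC and length offset (0.0162) and TPM (0.0105), so its call depends on the fit.

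Sterol synthesis transcripts fell together: of the cholesterol list, 0 of 23 measured members rose and 20 fell (0 and 22 adjusted over the list alone), with a median of -0.89 (camera adjusted p = 3.23e-38; adjusted p = 0.148 with an estimated correlation). MVD, mevalonate diphosphate decarboxylase, changed by -1.38 ± 0.092, LSS, lanosterol synthase, by -1.26 ± 0.092, and DHCR7 by -1.14 ± 0.094. Of the fatty acid list, 1 of 20 measured members rose and 12 fell (2 and 14 adjusted over the list alone; camera adjusted p = 4.95e-08, adjusted p = 0.264 with an estimated correlation), including ACSS2 at -1.43 ± 0.083, ACLY at -0.91 ± 0.082 and SCD at -0.66 ± 0.094. Of the proliferation list, 17 of 31 measured members rose and 0 fell (23 and 0 adjusted over the list alone; camera adjusted p = 2.30e-10, adjusted p = 0.264 with an estimated correlation). BUB1 was at 0.91 ± 0.12 and PCNA at 0.59 ± 0.084.

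Among targets of the YAP and TAZ coactivators, 7 rose and 1 fell of 16 measured members (8 and 4 adjusted over the list alone). YAP/TAZ target genes had a camera adjusted p = 0.0198 (adjusted p = 0.264 with an estimated correlation). CCN1 was at 2.44 ± 0.35 and CRIM1 at 0.61 ± 0.095. CCN2 rose by 0.77 ± 0.19, a call lost without control replicate 4, control replicate 5 or collagen replicate 4 (highest adjusted p 0.195). In the TGF-beta list, 8 rose and 2 fell of 18 measured members (10 and 3 adjusted over the list alone). TGF-beta genes had a camera adjusted p = 0.000332 (adjusted p = 0.211 with an estimated correlation). TGFBI was at 1.15 ± 0.089 and ID1 at 0.82 ± 0.10. In the list of matrix genes that HepG2 itself can express, 7 rose and 3 fell of 15 measured members (8 and 4 adjusted over the list alone). Basement membrane and own matrix genes had a camera adjusted p = 0.000332 (adjusted p = 0.264 with an estimated correlation). LOXL4 was at 2.44 ± 0.15, HSPG2 at 2.68 ± 0.20 and COL2A1 at -3.02 ± 0.41. In the interferon list, 7 rose and 1 fell of 25 measured members (11 and 1 adjusted over the list alone). Interferon genes had a camera adjusted p = 0.000217 (adjusted p = 0.264 with an estimated correlation). IFI27 was at 1.52 ± 0.22. In the hypoxia and glycolysis list, 6 rose and 1 fell of 22 measured members (6 and 1 adjusted over the list alone). Hypoxia and glycolysis genes had a camera adjusted p = 0.00319 (adjusted p = 0.349 with an estimated correlation). HK2 was at 1.22 ± 0.11. In the Wnt list, 7 rose and 3 fell of 17 measured members (8 and 4 adjusted over the list alone). Wnt target genes had a camera adjusted p = 0.00688 (adjusted p = 0.331 with an estimated correlation). DKK1 was at 2.00 ± 0.16 and DKK4 at -1.34 ± 0.17.

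In the epithelial junction list, 6 rose and 1 fell of 15 measured members (7 and 1 adjusted over the list alone). Epithelial junction genes had a camera adjusted p = 0.0205 (adjusted p = 0.349 with an estimated correlation). CLDN1 was at 1.19 ± 0.093. In the NF-kB and chemokine list, 8 rose and 2 fell of 17 measured members (8 and 4 adjusted over the list alone). NF-kB and chemokine genes had a camera adjusted p = 0.0247 (adjusted p = 0.264 with an estimated correlation). ICAM1 was at 0.78 ± 0.080 and CCL20 at -1.04 ± 0.13. In the p53 list, 7 rose and 1 fell of 19 measured members (7 and 1 adjusted over the list alone). P53 target genes had a camera adjusted p = 0.0230 (adjusted p = 0.264 with an estimated correlation). In the fibroblast marker list, 4 rose and 1 fell of 7 measured members (5 and 2 adjusted over the list alone). Fibroblast marker genes had a camera adjusted p = 5.17e-07 (adjusted p = 0.148 with an estimated correlation). The NF-kB list missed without control replicate 5 (adjusted p = 0.0568), with no filter (0.0542) and with the GC and length offset (0.0920), the junction list without collagen replicate 4 (0.0991) and the p53 list without collagen replicate 5 (0.0721). The fibroblast marker list rests on 7 measured genes led by TAGLN and by COL5A2 (1.88 ± 0.46), the latter chosen after its values were seen. On TPM the YAP/TAZ, matrix, NF-kB and fibroblast lists missed (adjusted p = 0.0557, 0.0844, 0.0753 and 0.206). Other lists that did not pass the camera test had adjusted p of 0.113 to 0.953. Notch counted 2 higher and 0 lower of 7 (2 and 0 adjusted over the list alone). Mesenchymal transition counted 2 higher and 2 lower of 14 (2 and 4 adjusted over the list alone). Collagen receptors and adhesion counted 3 higher and 1 lower of 22 (5 and 3 adjusted over the list alone). MAPK/ERK targets counted 1 higher and 5 lower of 19 (2 and 5 adjusted over the list alone). Stress response counted 3 higher and 6 lower of 25 (4 and 7 adjusted over the list alone). Oncofetal genes counted 0 higher and 3 lower of 9 (0 and 3 adjusted over the list alone). Mitochondrial mRNAs counted 0 higher and 0 lower of 13 (0 and 0 adjusted over the list alone). The adhesion list had a median of -0.046 and a mean of 0.090. It passed as higher by fry, which does not compare a list with other genes (adjusted p = 0.000423), and the junction list missed by fry (0.0514). Mitochondrial mRNAs passed as lower without collagen replicate 4 (adjusted p = 0.00709), with no filter (0.0159), with limma-voom (0.0353) and with the GC and length offset (0.0376). Among the members of these lists, ITGA2, an integrin subunit that binds collagen, changed by 1.25 ± 0.10 and ITGA10, another such subunit, by -1.13 ± 0.14. Of the mesenchymal list LGALS1 changed by 2.06 ± 0.16 and SPARC by -1.40 ± 0.084, and of the MAPK/ERK targets SPRY2 by -1.06 ± 0.15. Of the 3 endothelial and 4 leukocyte markers measured, EGFL7 at 3.83 ± 0.52 and CD3D at 3.86 ± 0.46 rose, with 1.51 ± 0.0542 and 2.29 ± 0.310 CPM in collagen.

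**Figure D1:**
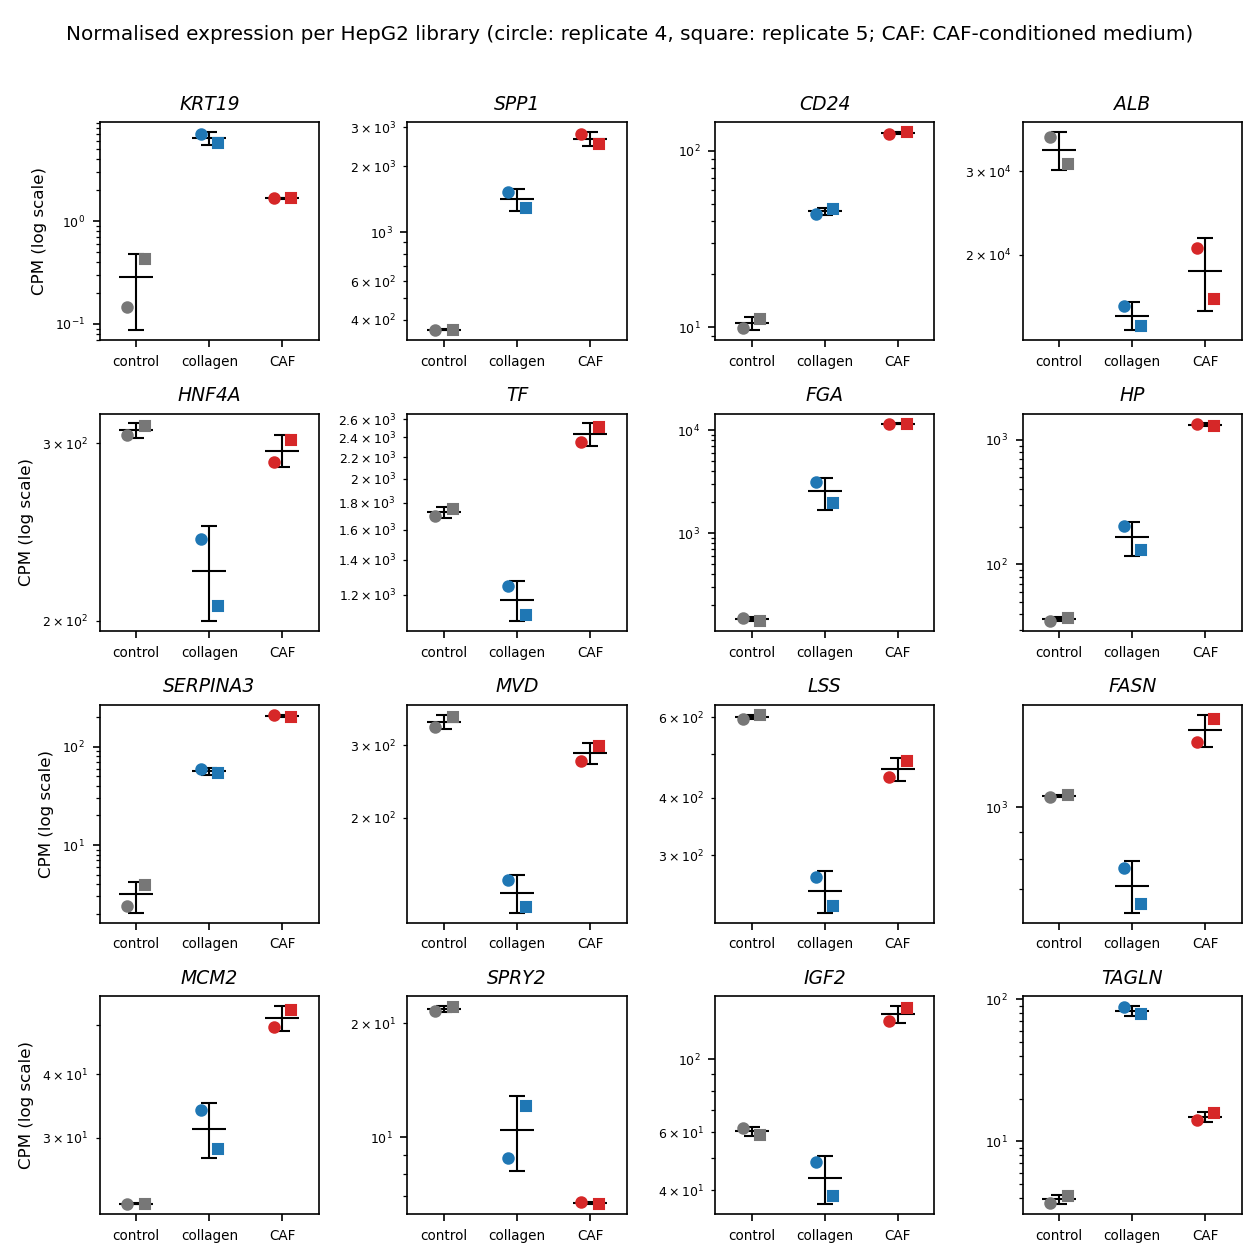
Normalised expression in CPM (log axis) of 16 genes in the 6 HepG2 libraries; symbols are single libraries, and bars are the group mean ± SD (n = 2). KRT19 was highest with collagen at 6.43 ± 0.896 CPM, SPP1 was highest with CAF medium at 2659.6 ± 194 CPM, and MVD was lowest with collagen.

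The collagen count depended on the controls: 1050 genes were called without control replicate 4 and 996 without control replicate 5, of which 1045 and 983 were among the 2499, and no called gene changed sign. On the authors' TPM without TMM factors, 1086 genes were higher and 565 lower, against 1222 and 1277 on counts.

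With CAF medium, 22 of 24 acute phase and 26 of 31 proliferation genes rose, and 10 of 19 MAPK/ERK targets fell. These lists passed at a preset but not at an estimated correlation (adjusted p = 0.135, 0.343 and 0.343 with an estimated correlation). FGA, the fibrinogen alpha chain gene (chromosome 4, 154583126 to 154590766, GRCh38), rose 78.9-fold from 146 ± 6.53 to 11552 ± 77.6 CPM (log2 6.30 ± 0.28, adjusted p = 3.73e-05, edgeR). NNMT, nicotinamide N-methyltransferase, had 2 counts in control and 2975 with CAF medium, a ratio of 1411 with a 95% counting interval of 390.1 to 11653. SPP1 rose 7.38-fold to 2659.6 ± 194 CPM and KRT19 5.92-fold to 1.67 ± 0.0191 CPM. From its low control level, the log2 fold change of KRT19 was 1.24 to 3.48 over the alternatives. In all, 5112 genes changed, 2660 higher and 2452 lower, and 1553 changed at least 2-fold.

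SOCS3 was at least 297-fold and LBP at least 176-fold higher than in control, where both had 0 counts. CXCL2 had a ratio of 314 (95% counting interval 55.9 to 12434), DNAH5 of 228, SLC38A8 of 195 and LRRK1 of 118, each with 1 or 2 counts in control. MATN3, a matrix protein gene, rose 106-fold and CA9, a carbonic anhydrase gene, 67.8-fold; the CA9 call was lost without control replicate 4 (highest adjusted p 0.0541). The largest falls were in PTGS1 (117-fold lower), DMRTC2 (80.5-fold), BANK1 (43.9-fold), LGR6 (38.0-fold), GRIA1 (35.5-fold), NEB (20.7-fold), the vitamin D binding protein gene GC (20.1-fold), SLC7A10 (19.1-fold), ITGA10 (17.8-fold) and the noncoding ROCR (16.7-fold). The calls of PTGS1 and GC were lost without CAF medium replicate 4 and without CAF medium replicate 5, with adjusted p of up to 0.0642 and 0.0891.

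Of the acute phase and STAT3 genes, 22 of 24 measured members rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 1.52, also with the genes at 0 in control at their bounds (camera adjusted p = 1.19e-46; adjusted p = 0.135 with an estimated correlation). SERPINA3 rose by 6.05 ± 0.18, CEBPD by 3.03 ± 0.13 and FGL1 by 1.82 ± 0.091. Of the proliferation genes, 26 of 31 measured members rose and 0 fell (26 and 0 adjusted over the list alone; camera adjusted p = 2.24e-16, adjusted p = 0.343 with an estimated correlation), among them BIRC5 at 1.42 ± 0.11 and RRM2 at 1.15 ± 0.10. Of the MAPK/ERK targets, 2 of 19 measured members rose and 10 fell (2 and 12 adjusted over the list alone; camera adjusted p = 0.000122, adjusted p = 0.343 with an estimated correlation). Those that fell included the feedback inhibitor genes SPRY2 at -1.70 ± 0.16 and SPRY4 at -1.09 ± 0.091, the transcription factor gene ETV4 at -1.34 ± 0.084 and EPHA2 at -1.43 ± 0.13.

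In the biliary list, 5 rose and 4 fell of 20 measured members (7 and 5 adjusted over the list alone). Biliary genes had a camera adjusted p = 0.00275 (adjusted p = 0.343 with an estimated correlation). CD24 rose by 3.57 ± 0.10 and ELF3 by 2.01 ± 0.20, whereas ANXA4 changed by -1.01 ± 0.090. EPCAM was at 0.21 ± 0.077 without passing, and SOX9 at -0.27 ± 0.088 passed with an adjusted p of 0.0357, lost without either control library or CAF medium replicate 4. In the hepatocyte list, 12 rose and 9 fell of 33 measured members (13 and 10 adjusted over the list alone). Hepatocyte genes had a camera adjusted p = 0.00248 (adjusted p = 0.535 with an estimated correlation). The median was -0.067 and the mean 0.57, so the median and the test differed in sign. The biliary and hepatocyte calls were lost with limma-voom (adjusted p = 0.225 and 0.351) and on TPM (0.228 and 0.317). That of the hepatocyte list was also lost with no filter (0.224) and by fry (0.0637). The largest rises of that list were in 4 acute phase genes, FGA, HP (5.18 ± 0.25), FGB (5.08 ± 0.25) and FGG (4.99 ± 0.17), of which HP and FGB were chosen after their values were seen. In contrast, ALB changed by -0.85 ± 0.13, SERPINC1 by -0.95 ± 0.095 and TTR by -1.31 ± 0.093. HNF4A was at -0.067 ± 0.088 without passing, and APOA1 and AFP passed at -0.36 ± 0.10 and -0.46 ± 0.13, the first lost without either control library or CAF medium replicate 4 and the second with only the 4 libraries compared and without any single library except CAF medium replicate 4. In the cholesterol list, 1 rose and 11 fell of 23 measured members (2 and 11 adjusted over the list alone). Cholesterol synthesis genes had a camera adjusted p = 0.0364 (adjusted p = 0.653 with an estimated correlation). LSS was at -0.38 ± 0.090; the list's call was lost without control replicate 5 (adjusted p = 0.0759) and by fry (0.0637), and that of LSS without either control library. The fatty acid list did not pass (7 higher and 4 lower of 20, 8 and 4 adjusted over the list alone, adjusted p = 0.420), with PLIN5 at 2.56 ± 0.27 and ACSS2 at -0.53 ± 0.081.

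In the Wnt list, 11 rose and 5 fell of 17 measured members (11 and 5 adjusted over the list alone). Wnt target genes had a camera adjusted p = 0.000561 (adjusted p = 0.343 with an estimated correlation). DKK1 was at 2.84 ± 0.16 and TNFRSF19 at 1.41 ± 0.087. In the matrix list, 8 rose and 2 fell of 15 measured members (8 and 3 adjusted over the list alone). Basement membrane and own matrix genes had a camera adjusted p = 0.000676 (adjusted p = 0.343 with an estimated correlation). LOXL4 was at 3.17 ± 0.15 and LAMB1 at 1.71 ± 0.081. In the hypoxia and glycolysis list, 12 rose and 2 fell of 22 measured members (13 and 2 adjusted over the list alone). Hypoxia and glycolysis genes had a camera adjusted p = 0.00880 (adjusted p = 0.461 with an estimated correlation). HK2 was at 1.42 ± 0.11 and VEGFA at -0.90 ± 0.094. In the interferon list, 9 rose and 1 fell of 25 measured members (9 and 2 adjusted over the list alone). Interferon genes had a camera adjusted p = 0.00880 (adjusted p = 0.437 with an estimated correlation). IFI27 was at 1.88 ± 0.21 and BST2 at 0.81 ± 0.10. In the junction list, 6 rose and 1 fell of 15 measured members (6 and 1 adjusted over the list alone). Epithelial junction genes had a camera adjusted p = 0.00880 (adjusted p = 0.369 with an estimated correlation). CLDN2 was at 4.01 ± 0.52 and DSP at 1.21 ± 0.089. In the NF-kB list, 6 rose and 3 fell of 17 measured members (6 and 3 adjusted over the list alone). NF-kB and chemokine genes had a camera adjusted p = 0.0200 (adjusted p = 0.343 with an estimated correlation). TNFAIP3 was at 1.39 ± 0.086 and LCN2 at 2.24 ± 0.15. In the TGF-beta list, 9 rose and 5 fell of 18 measured members (9 and 7 adjusted over the list alone). TGF-beta genes had a camera adjusted p = 0.0385 (adjusted p = 0.369 with an estimated correlation). In the p53 list, 9 rose and 3 fell of 19 measured members (10 and 3 adjusted over the list alone). P53 target genes had a camera adjusted p = 0.0405 (adjusted p = 0.369 with an estimated correlation). In the fibroblast marker list, 4 rose and 1 fell of 7 measured members (4 and 1 adjusted over the list alone). Fibroblast marker genes had a camera adjusted p = 0.0432 (adjusted p = 0.369 with an estimated correlation). Without control replicate 4 these last 3 lists no longer passed (adjusted p = 0.0634, 0.0630 and 0.0634). The p53 list also missed without collagen replicate 4 (0.0563) and collagen replicate 5 (0.0574), and the fibroblast list without CAF medium replicate 5 (0.116). The NF-kB, TGF-beta and fibroblast lists did not pass with limma-voom (adjusted p = 0.263, 0.214 and 0.187). With no filter the NF-kB and fibroblast lists missed (0.232 and 0.110). At a mean CPM of at least 1 the TGF-beta, p53 and fibroblast lists missed (0.0517, 0.0560 and 0.0913). With the GC and length offset the TGF-beta and fibroblast lists missed (0.0519 and 0.125). On TPM the NF-kB, TGF-beta and fibroblast lists did not pass (adjusted p = 0.244, 0.228 and 0.481), and the fibroblast median turned to -0.031.

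Other lists that did not pass with CAF medium had adjusted p of 0.179 to 0.901. YAP/TAZ targets counted 6 higher and 2 lower of 16 (6 and 5 adjusted over the list alone). Notch counted 2 higher and 0 lower of 7 (1 and 0 adjusted over the list alone). Of these, HES4 passed the gene test at an adjusted p of 0.0493, a call lost in 13 of 17 alternatives. Mesenchymal transition counted 5 higher and 3 lower of 14 (5 and 3 adjusted over the list alone). Collagen receptors and adhesion counted 6 higher and 6 lower of 22 (6 and 7 adjusted over the list alone). Stress response counted 6 higher and 9 lower of 25 (7 and 13 adjusted over the list alone). Oncofetal genes counted 4 higher and 3 lower of 9 (4 and 3 adjusted over the list alone). Mitochondrial mRNAs counted 2 higher and 0 lower of 13 (1 and 0 adjusted over the list alone). The adhesion list had a median of 0.042 and a mean of -0.12. By fry it passed as lower and the YAP/TAZ list as higher (adjusted p = 0.0368 and 0.0137). Mitochondrial mRNAs passed as higher with no filter (0.0342). CCN1 and CCN2 rose by 2.77 ± 0.34 and 2.30 ± 0.19, IGF2 by 1.18 ± 0.11 and PEG10 by 0.87 ± 0.12, and ITGA10 and ITGB3 changed by -4.16 ± 0.18 and -3.01 ± 0.41. In the same lists ITGA2 and FLNA went the other way at 1.20 ± 0.10 and 1.32 ± 0.090, and HMGA2 was at -0.51 ± 0.079. Of the endothelial markers 1 of 3 rose, EGFL7 at 3.55 ± 0.54, and of the 4 leukocyte markers FCER1G and LYZ fell. CD14 at 1.37 ± 0.47 passed with an adjusted p of 0.0419, lost with DESeq2, limma-voom, TPM, the GC and length offset, only the 4 libraries compared and without any single library except CAF medium replicate 5 (highest adjusted p 0.444). Without control replicate 4, 2803 genes were called, and without control replicate 5, 2951. Without CAF medium replicate 4, 2543 genes were higher and 2962 lower, and on TPM 1677 and 2005, against 2660 and 2452. Fold changes with CAF medium correlated with transcript GC content across 10877 genes (Spearman 0.28), which are not independent replicates; removing the GC and length trend kept 90.8% of the calls it could test.

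**Figure D2:**
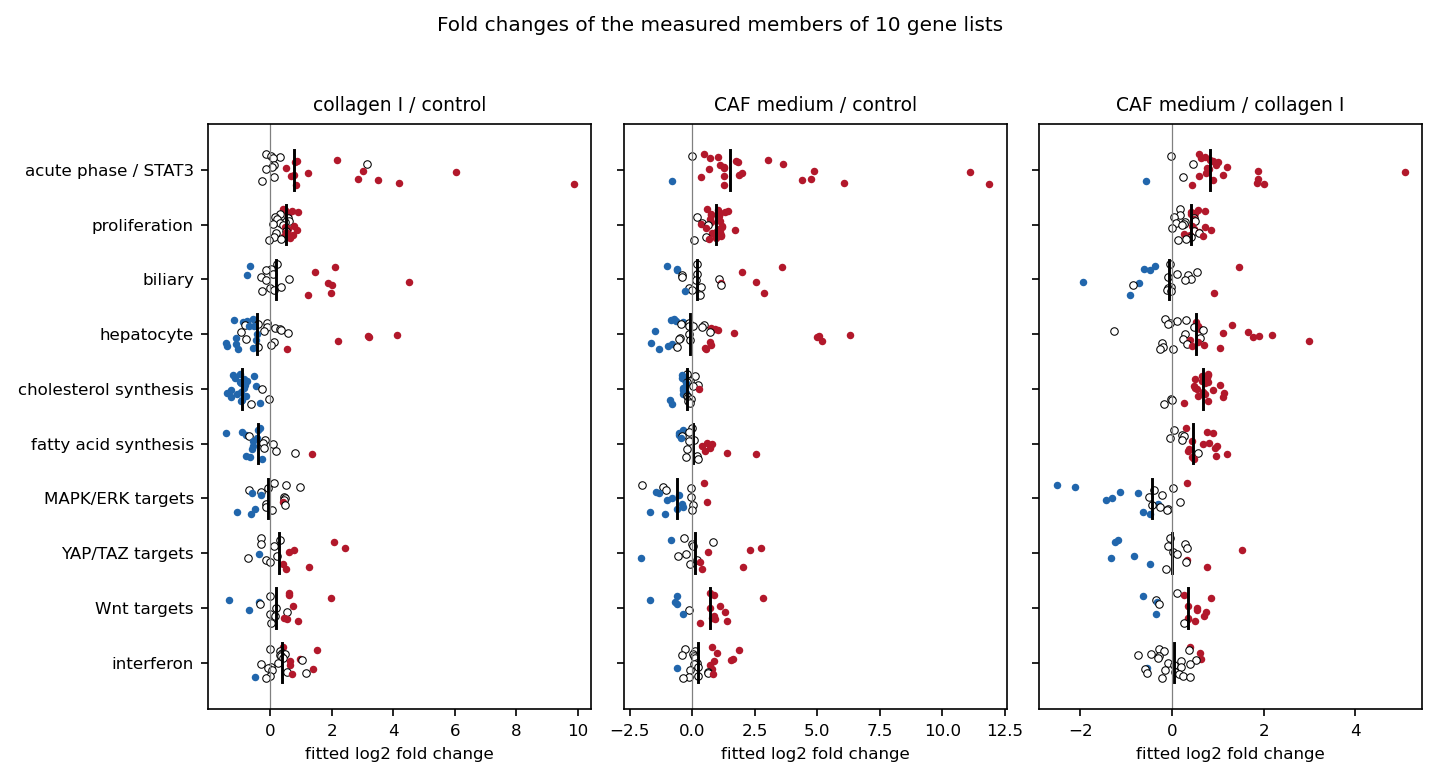
Fitted log2 fold change (x axis) of the measured members of 10 gene lists (y axis) in the 3 comparisons; filled red and blue points rose and fell at an adjusted p under 0.05, open points did not pass, and black lines are medians. Of the cholesterol list, 20 of 23 members fell with collagen and 20 were higher with CAF medium than with collagen.

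Compared directly, 20 of 23 sterol synthesis, 14 of 20 fatty acid and 17 of 33 hepatocyte genes were higher with CAF medium than with collagen, and KRT19 and TAGLN were lower. These lists passed at a preset but not at an estimated correlation (adjusted p = 0.351, 0.351 and 0.351 with an estimated correlation). Of the cholesterol list, 20 of 23 measured members were higher with CAF medium and 0 lower (20 and 0 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 4.17e-23; adjusted p = 0.351 with an estimated correlation). MVD was 1.13 ± 0.092 and LSS 0.88 ± 0.091 higher on the log2 scale. KRT19 was 3.84-fold lower (1.67 ± 0.0191 against 6.43 ± 0.896 CPM, adjusted p = 0.000331) and SPP1 1.88-fold higher (adjusted p = 0.000113). In all, 2664 genes differed, 1490 higher and 1174 lower with CAF medium, 603 of them at least 2-fold.

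NNMT had the largest rise over collagen, 145-fold to 71.1 ± 3.79 CPM, followed by LBP (33.6-fold), MATN3 (13.0-fold), DNAH5 (9.89-fold), LRRK1 (9.87-fold), HP, the haptoglobin gene (7.93-fold), CXCL2 (6.72-fold), SYT8 (5.76-fold), the noncoding TGILR (4.73-fold) and the antisense gene EVA1A-AS. The largest falls were in GRIA1 (51.8-fold lower), CRYAB (24.4-fold), PTGS1 (17.6-fold), DMRTC2 (15.5-fold), BFSP1 (13.0-fold), LGR6 (11.1-fold), SLC7A10 (9.89-fold) and GC (9.41-fold), and in the antisense genes DPP6-AS1 and KLRK1-AS1. Antisense counts are uncertain, since the counting strand is not given in the sources used here. The calls of PTGS1 and GC were lost without either CAF medium library and with limma-voom, and that of PTGS1 also without either control library and with no filter, with adjusted p of up to 0.241 and 0.2395. Those of LRRK1 and TGILR were lost on TPM (0.101 and 0.0530).

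Of the hepatocyte list, 17 were higher and 0 were lower of 33 measured members (21 and 2 adjusted over the list alone). Hepatocyte genes had a camera adjusted p = 2.36e-14 (adjusted p = 0.351 with an estimated correlation). The list holds acute phase genes such as HP (2.99) and FGG, and its median with CAF medium against control was -0.067. FGG was at 1.76 ± 0.15, TF, the transferrin gene, at 1.05 ± 0.095 and SERPINA1 at 0.71 ± 0.11; ALB at 0.31 ± 0.13 did not pass, and HNF4A at 0.40 ± 0.088 passed except without collagen replicate 5 and on TPM (highest adjusted p 0.0790). Of the fatty acid list, 14 were higher and 0 were lower of 20 measured members (17 and 0 adjusted over the list alone). Fatty acid genes had a camera adjusted p = 2.09e-12 (adjusted p = 0.351 with an estimated correlation). FASN was at 0.97 ± 0.10. Of the acute phase list, 20 were higher and 1 was lower of 24 measured members (20 and 1 adjusted over the list alone). Acute phase genes had a camera adjusted p = 6.29e-33 (adjusted p = 0.131 with an estimated correlation). ORM1 was at 1.10 ± 0.10. Of the proliferation list, 16 were higher and 0 were lower of 31 measured members (22 and 0 adjusted over the list alone). Proliferation genes had a camera adjusted p = 9.43e-08 (adjusted p = 0.435 with an estimated correlation). MCM2 was at 0.72 ± 0.11. Of the MAPK/ERK list, 1 was higher and 9 were lower of 19 measured members (1 and 11 adjusted over the list alone). MAPK/ERK target genes had a camera adjusted p = 3.69e-06 (adjusted p = 0.351 with an estimated correlation). IER3 was at -1.43 ± 0.15 and HBEGF at -1.32 ± 0.21. Of the Wnt list, 10 were higher and 3 were lower of 17 measured members (11 and 4 adjusted over the list alone). Wnt target genes had a camera adjusted p = 0.0147 (adjusted p = 0.435 with an estimated correlation). Of the oncofetal list, 3 were higher and 1 was lower of 9 measured members (4 and 2 adjusted over the list alone). Oncofetal genes had a camera adjusted p = 0.0147 (adjusted p = 0.435 with an estimated correlation). IGF2 was at 1.65 ± 0.11. Of the mitochondrial mRNAs, 4 were higher and 0 were lower of 13 measured members (8 and 0 adjusted over the list alone). Mitochondrial genes had a camera adjusted p = 0.00103 (adjusted p = 0.446 with an estimated correlation). Of the fibroblast markers, 1 was higher and 3 were lower of 7 measured members (2 and 3 adjusted over the list alone). Fibroblast marker genes had a camera adjusted p = 0.0165 (adjusted p = 0.351 with an estimated correlation). The oncofetal and fibroblast marker calls were lost without CAF medium replicate 4, each at an adjusted p of 0.103, and the latter also without collagen replicate 4 (adjusted p = 0.0880). Both were also lost with limma-voom (adjusted p = 0.0919 and 0.325) and on TPM (0.0797 and 0.194), and the latter with no filter (0.211). By fry the oncofetal and mitochondrial lists missed (0.0501 and 0.0525).

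The biliary list did not differ by the camera test (2 higher and 6 lower of 20, 3 and 6 adjusted over the list alone, adjusted p = 0.799), although CD24 was 1.47 ± 0.092 higher and KRT19 and CLDN4 (-0.62 ± 0.091) were lower. Other lists that did not pass between the treatments had adjusted p of 0.148 to 0.851. YAP/TAZ targets counted 3 higher and 5 lower of 16 (5 and 5 adjusted over the list alone). Notch counted 0 higher and 1 lower of 7 (2 and 2 adjusted over the list alone). TGF-beta counted 4 higher and 4 lower of 18 (4 and 4 adjusted over the list alone). Mesenchymal transition counted 3 higher and 4 lower of 14 (3 and 4 adjusted over the list alone). Epithelial junctions counted 3 higher and 1 lower of 15 (3 and 1 adjusted over the list alone). Collagen receptors and adhesion counted 2 higher and 4 lower of 22 (2 and 4 adjusted over the list alone). Own matrix counted 6 higher and 2 lower of 15 (7 and 3 adjusted over the list alone). NF-kB counted 3 higher and 3 lower of 17 (3 and 3 adjusted over the list alone). Interferon counted 3 higher and 1 lower of 25 (3 and 1 adjusted over the list alone). Hypoxia and glycolysis counted 2 higher and 3 lower of 22 (4 and 3 adjusted over the list alone). Stress response counted 5 higher and 5 lower of 25 (7 and 6 adjusted over the list alone). P53 targets counted 4 higher and 2 lower of 19 (6 and 3 adjusted over the list alone). CCN2 was 1.53 ± 0.18 higher and AMOTL2, another YAP/TAZ target, lower (-1.17 ± 0.13), while CCN1 at 0.33 ± 0.27, EPCAM at 0.11 ± 0.077, SOX9 at -0.023 ± 0.088 and AFP at 0.21 ± 0.13 did not pass, and APOA1 was 0.51 ± 0.10 higher. Of the endothelial markers 0 of 3 passed, and of the leukocyte markers CD3D (-2.65 ± 0.38) and LYZ (-0.44 ± 0.083) were lower. The median and mean differed in sign for the Notch, TGF-beta, matrix, interferon and stress lists. By fry the adhesion list passed as lower and the NF-kB list as higher (adjusted p = 7.50e-05 and 0.0165). The adhesion list also passed on TPM (0.0219) and the junction list with no filter (0.0230). Without collagen replicate 5, 1156 genes were called, and without control replicate 5, 1747. On TPM the median of all genes shifted to -0.13 and 453 genes were higher and 997 lower. Without CAF medium replicate 4, 1674 genes were higher and 2187 lower, while RLE normalization alone gave 1436 and 1167. The TPM setting used no TMM factors and also changed the transform, the filter and the test. TMM factors were 1.03 and 1.06 with collagen and 0.960 and 0.971 with CAF medium. Leaving these out lowers CAF medium against collagen, the way the median moved, and RLE also scales between libraries. How much of the shift each change gave was not tested. The fold changes correlated with transcript GC content across genes (Spearman 0.42), and 86.9% of the testable calls held after the trend was removed.

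Across the 16115 genes, the changes with collagen and with CAF medium tended to go the same way, with a Pearson correlation of 0.722 and a covariance of 0.361. In 20 simulations of unchanged groups that shared a simulated control group, the medians were 0.515 (0.482 to 0.538) and 0.0453 (0.0411 to 0.0490). The sign was the same in 73.7% of genes, against a simulated median of 66.7%. The simulations drew each gene independently and held no GC or length trends between libraries. The covariance exceeded the simulated median by 0.315. Genes are not independent replicates, and the 2 control libraries, shared by both comparisons, could not be split between them. Of the called genes, 951 rose in both comparisons and 872 fell in both, against 0 to 1 each in the simulations. Unchanged groups give almost no calls, so this does not show how far separate changes would overlap. Among the 951, the rise was larger with CAF medium in 315 and smaller in 18 by the direct test, and among the 872 the fall was deeper in 217 and shallower in 46. The correlation was 0.566 without collagen replicate 4, 0.628 without CAF medium replicate 4 and 0.546 with no filter on low counts.

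**Figure D3:**
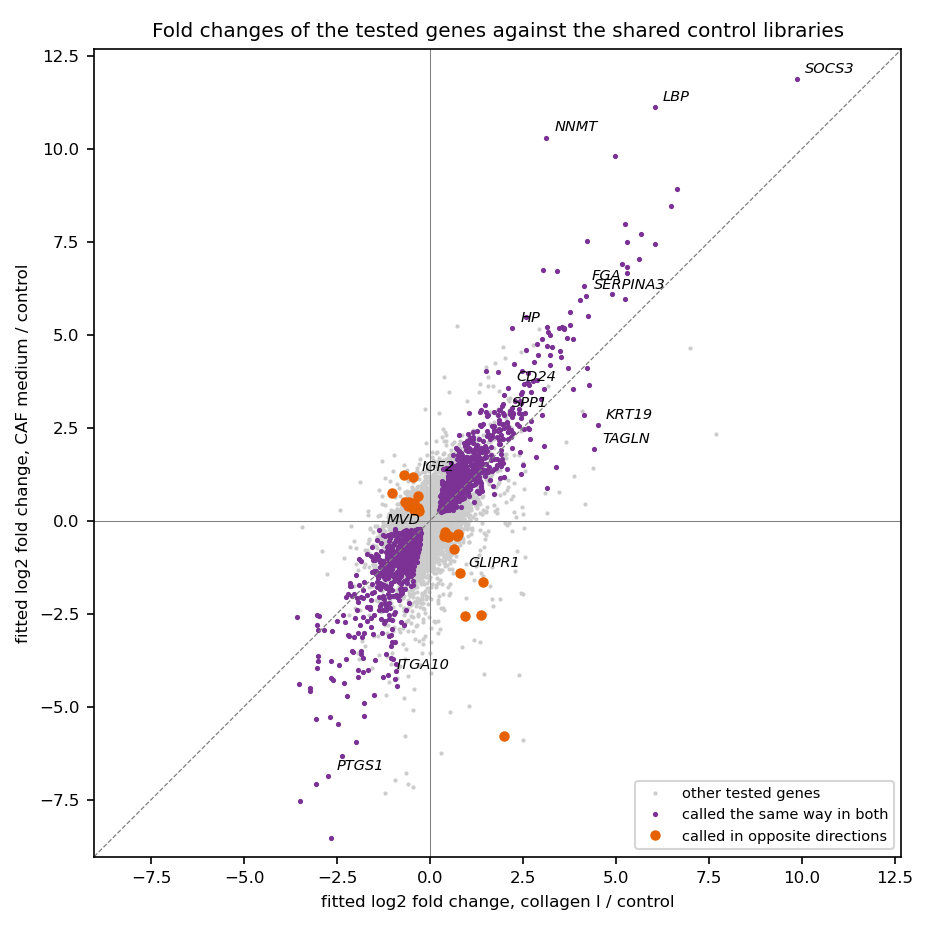
Fitted log2 fold change against control of the 16115 tested genes with collagen (x axis) and CAF medium (y axis), each point a gene; purple genes passed in the same direction in both (951 rose and 872 fell) and orange genes passed in opposite directions with a passing difference (26). Fitted values of genes with no counts in control, such as SOCS3, depend on the prior count, and the dashed line marks equal changes.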

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

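The tests of mixed libraries and of carried-over fibroblasts were chosen after the results were seen. Of the genes called in both comparisons, 26 were called in opposite directions and also differed between CAF medium and collagen by the direct test, 12 higher with collagen and 14 higher with CAF medium. The iron carrier gene TF changed by -0.56 with collagen and 0.50 with CAF medium, a difference of 1.05 ± 0.095, and the growth factor gene IGF2 by -0.47 with collagen and 1.18 with CAF medium, a difference of 1.65 ± 0.11. The IGF2 fall with collagen was lost without control replicate 4, control replicate 5 or collagen replicate 5 and on TPM. ACSL1, an acyl-CoA synthetase gene, differed by 1.06 ± 0.089, LEAP2 by 1.19 ± 0.15 and SLC30A3 by 1.76 ± 0.28. GLIPR1 differed by -2.21 ± 0.23, CEMIP by -1.14 ± 0.11, CYSTM1 by -1.12 ± 0.10 and the uncharacterised LOC124900418 by -3.09 ± 0.16. Against control the edgeR adjusted p of SLC30A3 was 0.0373 with collagen and 0.0437 with CAF medium, near the threshold. That of GLIPR1 was 0.0278 and 0.00163, and that of LOC124900418 3.47e-05 and 1.37e-05. Opposite calls make a passing difference likely, so the direct test adds little to them. The pseudogene ACSL3P1 differed by 1.93 ± 0.16, and its counts are uncertain where reads are shared with its parent gene.

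The changes with collagen and CAF medium tended to go the same way across genes, with a covariance of 0.361. In 20 simulations of unchanged groups that shared a simulated control group the highest covariance was 0.0490. Shared controls thus account for part of the covariance in this model but not for the whole. The model held no GC or length trends between libraries, so it does not bound what these control libraries could add. With the GC and length offset the correlation of both effects was 0.734. RNA of CAF medium libraries mixed into the collagen libraries would bring every gene at the same share, but NNMT allows a share of at most 1.04% (upper 95% limit), against a median of 67.4% for the 951 genes that rose in both. A response of HepG2 that both treatments evoke remains a hypothesis, and a difference in culture time or handling of the control cultures was not tested.

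The 2 CAF medium libraries differed more from each other than the 2 control libraries. Their log2 ratio correlated with GC content at Spearman -0.53 across 10877 genes, against -0.41 in the control pair and 0.46 in the collagen pair, and GC content and length explained 38.7%, 15.1% and 22.7% of its variance. A GC-related technical difference between the libraries is thus a candidate explanation for part of this spread. No biological explanation was tested, since the labels give none within a group.

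NNMT and other genes nearly absent from control rose with CAF medium. If fibroblasts had been carried over with the medium, their markers would have risen too. The 15 fibroblast markers nearly absent from control had 13 counts together in the CAF medium libraries, 0.437% of the 2975 NNMT counts. They had 24 counts in the collagen and 8 in the control libraries. Of these markers 9 had 0 counts in all 6 libraries, as had VIM. Whether reads could be counted for them was not checked, so only the other 6 were relied on. Among these was COL3A1 with 0 counts in the CAF medium libraries. Some markers that HepG2 already expressed in control rose with CAF medium, TAGLN by 1.93, FBN1 by 1.97, COL5A2 by 1.58 and ACTA2 by 1.34, while PDGFRB fell by 1.02. TAGLN rose more with collagen (4.41), where no conditioned medium was added. The low counts argue against carried-over fibroblasts as the source of NNMT. The changes of the expressed markers were not assigned to a cause, and a response of HepG2 to the medium remains a hypothesis.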

How the results depend on the processing

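The TPM, GC offset and crossed block settings were chosen after seeing the data. Total counts of called genes stayed within 1.5 times under RLE normalization, no filter, a mean CPM of at least 1, DESeq2 (2001, 4259 and 2226), limma-voom (2467, 5095 and 2656) and the GC and length offset (3124, 5600 and 3076), for collagen against control, CAF medium against control and CAF medium against collagen. With no filter the genes lower with CAF medium than with collagen moved further, to 1769 against 1174. Leaving out 1 library gave 996 to 3274, 2803 to 5505 and 1156 to 3861 genes; the lone library of a group was then assumed to vary like the others. At least 2-fold changes numbered 675, 1553 and 603, TPM gave 1651 and 1450 in the first and last comparison, and only the 4 libraries compared gave 1697 in the last; apart from the stricter fold limit and the fewer libraries, the cause was not tested. The correlation of both effects was 0.546 with no filter, and 0.566 to 0.738 with 1 library left out. With an estimated correlation 0, 0 and 0 lists passed, against 15, 15 and 10 at the preset correlation. That setting also tests with 3 degrees of freedom, so these misses cannot be put down to gene correlation alone. The limma-voom, no filter, TPM, GC and length offset and fry settings also end or add single list calls, which the results give with their values. With only the 4 libraries compared, the TGF-beta and p53 lists missed for CAF medium against control (adjusted p = 0.0654 and 0.0679), and with the GC and length offset the adhesion list passed for collagen against control (0.0389). The hepatocyte list, collagen against control, was reversed without collagen replicate 5 (median -0.36, adjusted p = 0.0126, range of medians -0.50 to -0.36 with 1 library left out): the test pointed up while the median stayed negative; the cause was not tested. Values that no fit called, and genes without an adjusted p in DESeq2, were counted as the same when their sign changed; lists were not run in DESeq2. In simulations with 200 genes changed 8.59% to 10.3% of calls were false on average, so calls near the threshold may be less certain than their adjusted p states. Far more genes were called here than were changed in the simulations, so this false share need not carry over to these data. The replicate block gave 2035, 4598 and 2134 genes. It ended the TGF-beta, p53 and fibroblast list calls for CAF medium against control (adjusted p = 0.0510 each) and the CA9 call for collagen against control. Across 7913 genes with a mean log2 CPM over 4, differences between replicates correlated between groups at -0.26, 0.35 and -0.38. These are control with collagen, control with CAF medium, and collagen with CAF medium. Over all tested genes the values were -0.016, 0.090 and -0.148. The GC trends between replicates (-0.41 in control, 0.46 with collagen, -0.53 with CAF medium) go with these signs, so the correlations do not settle pairing. The numbers were not read as pairs. A crossed replicate block gave 2874, 5817 and 3493 genes; for collagen against control the hepatocyte list then passed as lower (median -0.42, adjusted p = 0.0165) and the PTGS1 call was lost, and for CAF medium against collagen the PTGS1 and GC calls were lost.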

Other observations

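Of the genes called with CAF medium but not with collagen, 1363 also differed between the treatments by the direct test, and 308 did so the other way round.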
